A study of Mus musculus with 12 samples.

How the data were processed

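Total RNA from the livers of 12 male C57BL/6 mice was measured, 1 array per mouse, on 1-colour Agilent arrays of 60-base probes labelled with Cy3, per the labels. The labels give 4 groups of 3 biological replicates, Sirt1 wild type (WT) or heterozygous (Het) kept for 34 weeks on food either low or high in fat. The deposited scanner tables hold intensity values made with Agilent Feature Extraction 9.5, per the submitters' processing notes. Per the file headers, the processed intensity of a spot is its brightness after background subtraction and detrending within the array, with a surrogate value where a spot did not exceed the background. The raw mean intensity and the local background intensity stand beside it, per the file headers, as do flags of 0 or 1 for spots well above background, saturated or outlying, which have no unit of their own. No normalization between arrays is recorded in the file headers.

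The deposited table of the whole series was set against the scanner tables spot by spot and held the same processed intensity values, on a linear scale, not centred. Its medians over non-control spots were 86.3, 117.1 and 78.3 on the WT high-fat arrays, 80.2, 83.2 and 114.6 on the Het high-fat arrays, 142.1, 95.2 and 129.9 on the WT low-fat arrays, and 142.4, 163.4 and 101.8 on the Het low-fat arrays. It is therefore no independent alternative.

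The processed intensity of each spot was taken as log2 and the log2 of the 75th percentile over the non-control spots of its array was subtracted, so that all levels are log2 values relative to that percentile. Control spots were left out, as were outlier-flagged spots, 1344 over all arrays, while saturated spots were kept. Spots of 1 probe were averaged, giving 41174 probes. A probe was kept where it was well above background on all arrays of at least 1 group and had values on at least 2 arrays of every group, which left 25297 probes. Probes were named through their accession (22951 probes), a current symbol (6659) or an older symbol (3109) in a table of RefSeq genes, and 8455 kept the name of the array design, which can be old. Where a gene had several probes, as 5903 genes did, the one with the highest mean signal was used. In all 17043 genes or transcripts were tested, 14451 of them with a current symbol. Probe coordinates are those of the array design on mm7, per the file headers.

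Differences were fitted with limma 3.58.1 in R 4.3.3, as means of the 4 groups with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The fit had 8 residual and 2.8 prior degrees of freedom. The 6 comparisons were diet in WT, diet in Het, genotype on the high-fat diet, genotype on the low-fat diet, genotype over both diets, and the interaction of genotype and diet. Sirt1 was also tested by exact two-sided permutation. Gene lists for pathways and cell types, 35 in all, were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with a correlation estimated from the residuals. Of these, 34 had at least 5 measured genes, and the list of pancreatic acinar cells, with 4 of 12 genes measured, was not tested. P-values of lists were adjusted over the 34 lists of a comparison. Of 53 calls over the 6 comparisons 2 held with the estimated correlation, acute phase genes with diet in WT and with genotype on the low-fat diet. Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

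Named genes are every Sirt1 probe, the 8 largest increases and 8 largest decreases among called genes with a current symbol whose groups did not overlap, and up to 4 members of lowest p in each list that was called or held a called gene. Where fewer than 5 genes passed, the 5 of lowest p in each direction are named as not passing. Not every gene that this rule names is reported here.

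Data were simulated with normal noise, at the moderated spread that the fit gave each gene, and with 200 changed genes per comparison. The test recovered 63.9% of 2-fold and 97.4% of 4-fold changes for diet in WT, and 54.3% and 94.2% for diet in Het. It recovered 56.9% and 95.2% for genotype on the high-fat diet, 54.7% and 95.9% on the low-fat diet, 89.3% and 98.4% over both diets, and 19.4% and 77.1% for the interaction. Of 1.5-fold changes it recovered 12.7% for diet in WT, 14.8% for diet in Het and 0% for the interaction. For genotype these were 10.6% on the high-fat diet, 9.52% on the low-fat diet and 53.1% over both. Between 3 and 13 of 16843 unchanged genes were called. A list shifted by -0.5 was called in each of the 6 comparisons and 0 of 33 other lists were. The genes were simulated independently of one another, with no trend or difference shared by the genes of an array. The recovery and false calls of single genes therefore hold only for arrays without such trends. Nor can the simulation show how often lists of correlated genes are called without a shift.

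The arrays lay on 4 slides, scanned on 2 days. One slide held 2 WT high-fat arrays, another the third WT and all Het high-fat arrays, another all WT and 1 Het low-fat array, and the last 2 Het low-fat arrays. Each slide and each scan day held 1 diet, so slide entered diet comparisons as a random block and genotype comparisons as a fixed block. Alternatives were background correction with normexp at an offset of 50, quantile normalization, scaling to the median, other filters on dim probes, outlier spots kept, other ways to combine probes, a trend and robust variance model, only the compared groups in the fit, slide and replicate number as blocks, and leaving out each array in turn. Added after the data were seen were the omission of probes with runs of alternating G and T bases, the removal of each array's trends on probe GC content and brightness, array brightness or background noise as a covariate, and slide as a fixed block for the interaction.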

Results

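Liver RNA from 12 male C57BL/6 mice was measured on 1-colour microarrays, on which the brightness of each short DNA probe reports the abundance of 1 transcript. The mice were either wild type for Sirt1 (WT) or carried 1 intact copy (Het), and were kept for 34 weeks on food either low or high in fat. Each of the 4 groups held 3 mice with 1 array each, so n = 3 per group in every comparison. Sirt1 encodes an NAD-dependent protein deacetylase, and the series asks what its dose does in metabolic disease brought on by diet. Between 58.0% and 71.6% of the spots of an array lay well above background, and the 75th percentile of the processed signal ran from 975.1 to 2006.4 intensity units. The number of arrays limits the precision. The first principal component held 41.6% of the variance and parted the diets, with scores from -57.6 to -21.7 on the high-fat arrays and from 24.4 to 42.8 on the low-fat arrays. All 6 high-fat arrays were scanned on 1 day and all low-fat arrays on another, on separate slides. Diet and scan day therefore cannot be told apart in any diet comparison here.

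Sirt1 itself was lower in Het than in WT livers on both of its probes, which checks the genotype labels. The probe with the brighter signal lies at 62855795 to 62855854 of chromosome 10 in mouse build mm7, per the file headers, and the other at 62838289 to 62838348. Over both diets the brighter probe gave a log2 difference of -0.44 ± 0.09 (SE), or 73.8% of the WT level, and the other probe -0.64 ± 0.09, or 64.1%. In an exact two-sided permutation test stratified by diet, each reached p = 0.005, the smallest value that the 400 arrangements can give. Within 1 diet no exact test of 3 mice against 3 can go below p = 0.1, and each probe reached that value on each diet. The part of Sirt1 removed from the Het allele is not given in the sources used here, so whether a probe lies inside it is open. On the slides that held both genotypes the brighter probe differed by -0.54 ± 0.21 on the high-fat and -0.40 ± 0.21 on the low-fat diet with slide as a block, and the other probe by -0.72 ± 0.21 and -0.58 ± 0.21. Across the 17043 genes tested the Sirt1 difference over both diets had an adjusted p of 0.972. Between the diets, the brighter probe differed by -0.30 ± 0.13 in Het (adjusted p = 0.145 over all probes) and by -0.29 ± 0.13 in WT (adjusted p = 0.196), and so did not pass. The dimmer probe differed by -0.50 ± 0.13 in Het (adjusted p = 0.0305) and by -0.41 ± 0.13 in WT (adjusted p = 0.088).

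**Figure D1:**
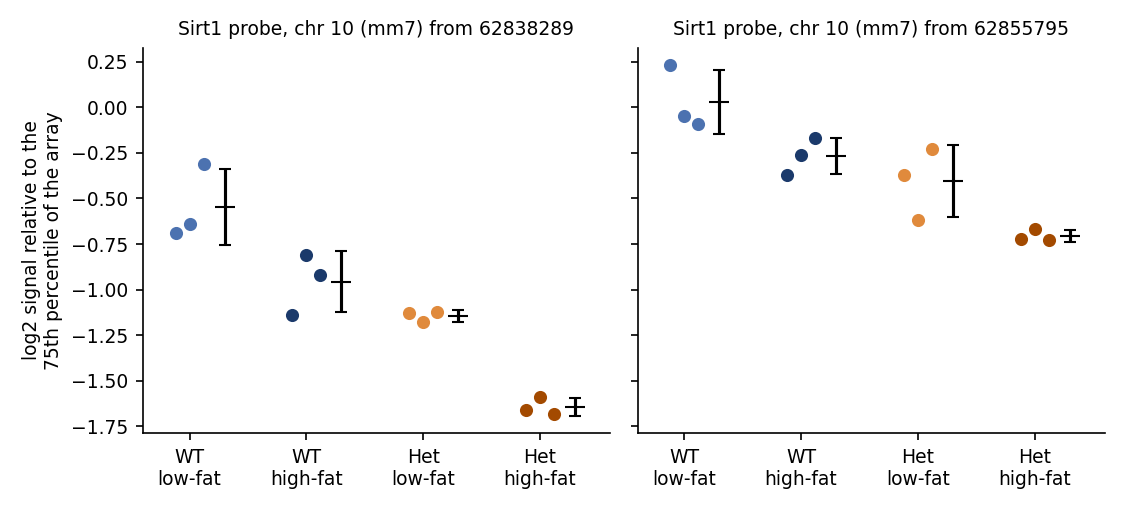
Signal of the 2 Sirt1 probes on each of the 12 arrays, as log2 of the signal relative to the 75th percentile of the array, with 1 point per mouse and the mean ± SD of each group of 3 beside it. On the dimmer probe the Het low-fat mean was -1.14 against -0.54 in WT, and the Het high-fat mean -1.64 against -0.96.

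The first comparison asks what the high-fat diet did in WT livers. Genes of collagen and stellate cells, lipid droplets, cholesterol synthesis, the acute phase response and macrophages and Kupffer cells were higher as lists, and male-biased liver genes were lower. Of these lists only that of the acute phase response also passed with an estimated correlation. Among single genes, Tinag, a protein of basement membranes, rose by a log2 fold change of 4.81 ± 0.67 (SE; adjusted p = 0.0104). The actin-bundling gene Pls1 rose by 4.56 ± 0.85 and the PDZ domain gene Gipc2 by 4.09 ± 0.71. Increases of the same order were those of the orphan receptor gene Gprc5b (3.83 ± 0.70), the surface antigen gene Ly6d (3.64 ± 0.61) and the ephrin receptor gene Ephb2 (3.58 ± 0.73). Gpnmb and Mmp12, both products of activated macrophages, rose by 4.04 ± 0.60 and 3.76 ± 0.48. On the WT low-fat arrays Pls1 was well above background on 2 of 3, and Tinag, Gipc2, Gpnmb and Mmp12 on 1 of 3. The folds of these 5 genes therefore rest partly on signals near the background. Moxd1, a monooxygenase gene with male-biased expression in mouse liver, was well above background on every WT low-fat array and on no WT high-fat array. It was at least 17.4-fold lower (adjusted p = 0.00749). Such a bound sets the mean of the bright group against, per array, the higher of the dim probe's own signal and the lowest signal well above background. Hamp, which encodes the iron hormone hepcidin, had a log2 fold change of -3.97 ± 0.64, the steroid dehydrogenase gene Hsd3b4 of -3.60 ± 0.66 and the adhesion receptor gene Adgrf1 of -3.18 ± 0.37. Hsd3b4 has close relatives, so its signal as a single gene is uncertain. The other 4 of the 8 largest decreases, Stag2, Dennd3, Gast and Olfr1410, came from probes with runs of 11, 9, 9 and 8 alternating G and T bases, and are given with those probes further on.

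Of 20 measured genes of fibrosis and stellate cells, 4 rose over all genes tested and 13 adjusted over the list alone. They were led by the fibrillar collagen gene Col5a2 (1.14 ± 0.23), the growth factor receptor gene Pdgfrb (0.88 ± 0.17) and Col1a1 (2.07 ± 0.48). The list had adjusted p = 2.99e-07, and adjusted p = 0.316 with an estimated correlation. Of 23 genes of cholesterol synthesis and uptake, 6 rose (12 adjusted over the list alone). The squalene synthase gene Fdft1 stood at 0.72 ± 0.16 and the lanosterol synthase gene Lss at 0.96 ± 0.22 (list adjusted p = 1.92e-06; adjusted p = 0.316 with an estimated correlation). Of 16 lipid droplet and PPARG target genes, 6 rose and 9 did so adjusted over the list alone, 1 other falling there. Fabp4, a fatty acid carrier, stood at 1.76 ± 0.28 and Pparg itself at 1.20 ± 0.20 (list adjusted p = 3.36e-05; adjusted p = 0.316 with an estimated correlation). Of 19 fatty acid synthesis genes only Gpam, the first step of glycerolipid synthesis, rose over all genes (1.51 ± 0.33). In all, 3 did so adjusted over the list alone (list adjusted p = 0.000104; adjusted p = 0.403 with an estimated correlation). Of 5 measured adipocyte markers 3 rose, and 4 adjusted over the list alone. They were Fabp4, the lipid droplet gene Cidec (3.04 ± 0.74) and Aqp7, which was well above background on 2 of 3 WT high-fat arrays and no low-fat array, and was at least 2.28-fold higher. The list was called (list adjusted p = 0.000746; adjusted p = 0.316 with an estimated correlation). Hepatocytes also express Cidec and Fabp4 when they store lipid, and Fabp4 and Cidec stand on the lipid droplet list too.

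The acute phase response list, proteins that the liver secretes in inflammation, was the 1 list of this comparison that also passed with an estimated correlation. Of its 23 genes 8 rose, and 9 rose and 1 fell adjusted over the list alone (list adjusted p = 4.24e-05; adjusted p = 0.0362 with an estimated correlation). Saa1 rose by 2.05 ± 0.35 and Saa2 by 2.01 ± 0.35, near-identical genes whose signals are uncertain one by one, and the haem carrier gene Hpx rose by 0.67 ± 0.13. Of 23 macrophage and Kupffer cell genes 3 rose, Mmp12, Gpnmb and Trem2 (2.23 ± 0.41), and 6 adjusted over the list alone (list adjusted p = 0.000104; adjusted p = 0.403 with an estimated correlation). Of 19 cytokine and NF-kB target genes 3 rose, among them the monocyte chemoattractant gene Ccl2 (1.68 ± 0.32) and Tlr2 (1.11 ± 0.23). That number was 5 adjusted over the list alone (list adjusted p = 0.000972; adjusted p = 0.421 with an estimated correlation). Of 20 proliferation genes 3 rose and 6 adjusted over the list alone, led by the replication gene Mcm6 (0.85 ± 0.19) and the mitotic kinase gene Aurka (1.09 ± 0.25). The third was Cdkn1a (1.90 ± 0.44), which encodes an inhibitor of the cell cycle (list adjusted p = 2.28e-05; adjusted p = 0.417 with an estimated correlation). Of 17 NRF2 target genes 3 rose and 4 adjusted over the list alone. Srxn1 stood at 1.13 ± 0.14 and Cbr3 at 2.02 ± 0.29 (list adjusted p = 0.00403; adjusted p = 0.421 with an estimated correlation). Without WT low-fat replicate 2 this list had adjusted p = 0.099. Of 12 genes of glycolysis and glucose uptake 1 rose and 2 did so adjusted over the list alone, while the phosphofructokinase gene Pfkl, at 0.48 ± 0.13, did not pass over all genes (adjusted p = 0.0575; list adjusted p = 0.00113; adjusted p = 0.316 with an estimated correlation). None of 9 cholangiocyte markers passed over all genes and 2 did adjusted over the list alone. The lowest p was that of Spp1 at 1.64 ± 0.46 (list adjusted p = 0.00592; adjusted p = 0.434 with an estimated correlation).

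Of 18 male-biased liver genes 5 fell, and 8 adjusted over the list alone, Moxd1 and the complement gene C8b (-1.19 ± 0.23) having the lowest p (list adjusted p = 0.000141; adjusted p = 0.403 with an estimated correlation). Of 15 female-biased liver genes 4 rose, and 8 adjusted over the list alone (list adjusted p = 8.92e-05; adjusted p = 0.341 with an estimated correlation). Cyp3a44 rose by 1.06 ± 0.26 and Cyp3a16 by 1.02 ± 0.25, members of a near-identical family and uncertain as single genes. Of 18 genes of bile acid synthesis and transport Cyp7b1 fell (-1.28 ± 0.29), and 3 fell adjusted over the list alone (list adjusted p = 0.0147; adjusted p = 0.536 with an estimated correlation). The bile acid call was lost without WT high-fat replicate 2 or WT low-fat replicate 2 (adjusted p up to 0.147). None of 15 T and NK cell genes passed alone, Ptprcap standing at -0.48 ± 0.15, while the list was lower (list adjusted p = 0.0285; adjusted p = 0.652 with an estimated correlation). That call was lost without WT high-fat replicate 3 or WT low-fat replicate 1 (adjusted p up to 0.167). The lists of LXR targets, fatty acid oxidation and PPARA targets, gluconeogenesis, steroid hormone metabolism, xenobiotic metabolism, the circadian clock, sirtuins and NAD metabolism, oxidative phosphorylation, lipoproteins, interferon-stimulated genes, ER stress, heat shock proteins, immediate early genes, B cells, neutrophils, endothelial cells, hepatocytes and red blood cells were not called, with adjusted p between 0.0937 and 0.735. Among the hepatocyte genes Cps1, an enzyme of the urea cycle, fell by 1.12 on the log2 scale, and among the ER stress genes Atf3 rose by 1.73 ± 0.31.

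In the limma fit 1009 genes changed with diet in WT, 466 higher and 543 lower, of which 229 and 236 by at least 2-fold. The split depended on the scaling: 46.2% of the called genes were higher as reported. It was 61.8% with quantile normalization, 74.6% with scaling to the median, and 60.5% with each array's trend on probe GC content and brightness removed, an alternative added after the data were seen. Scaling to the median moved the median change of all genes from -0.05 to 0.07. The count was 156 without a filter on dim probes, where more genes were tested, 549 with replicate as a block, 598 with only the 2 groups in the fit and 3595 with slide as a random block. It fell to 254, 245 and 186 without WT high-fat replicates 1, 2 and 3, to 208 and 346 without WT low-fat replicates 1 and 3, and to 670 and 665 without Het low-fat replicates 1 and 2. Diet differed only between slides, and the correlation estimated within slides was negative (-0.18). This makes diet differences look more precise, so the 3595 genes are no stronger evidence. In all 16 of the 52 called genes named in the text passed whichever array was left out. The calls of Cyp3a44 and Cyp3a16 were each lost without any 1 of 9 arrays, and that of Aqp7 without any 1 of 8.

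**Figure D2:**
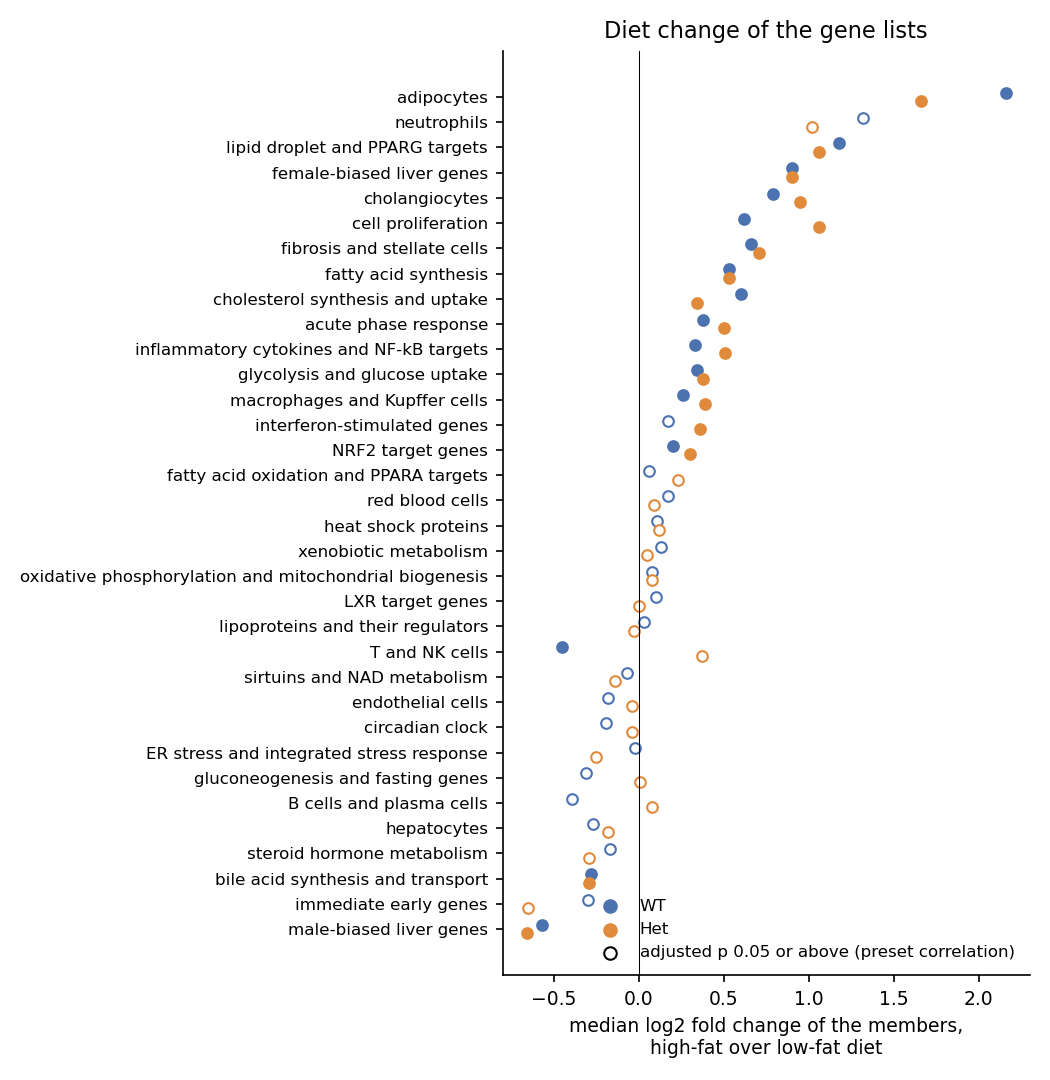
Median log2 fold change, high-fat over low-fat diet, of the measured members of each gene list in WT and in Het livers, with filled points where the list had an adjusted p below 0.05 with the preset correlation. The adipocyte list had the highest median in both genotypes, 2.16 in WT and 1.66 in Het, and the male-biased list the lowest, -0.57 and -0.66.

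The same question was asked of Het livers. Cell cycle, collagen, lipid droplet, female-biased and macrophage genes were higher as lists on the high-fat diet, and male-biased genes lower. None of the lists called here passed with an estimated correlation. Tinag was well above background on no Het low-fat array and was at least 12-fold higher (adjusted p = 0.00311). Ly6d rose by 4.54 ± 0.61, Gipc2 by 4.25 ± 0.71, Gprc5b by 3.51 ± 0.70 and Cidec by 3.47 ± 0.74, and the syntenin family gene Sdcbp2 by 3.97 ± 0.70. Elovl7, a fatty acid elongase gene, and the meiosis gene Hormad2 were also well above background on no Het low-fat array and were at least 8.13-fold and 3.6-fold higher. Gipc2 was well above background on 2 of 3 Het low-fat arrays. The steroid dehydrogenase genes Hsd3b4 and Hsd3b5 had the largest decreases, -6.64 ± 0.66 and -6.62 ± 0.82, and their close sequences leave them uncertain as single genes. Moxd1 was well above background on 2 of 3 Het low-fat arrays and no Het high-fat array, and was at least 4.46-fold lower. The organic anion transporter gene Slco1a1 had a log2 fold change of -3.40 ± 0.55. Itgb3, Bcorl1, Olfr1410 and Dennd3 completed the 8 largest decreases, all on probes with runs of alternating G and T bases.

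Of 20 proliferation genes 11 rose, and 16 adjusted over the list alone, led by the kinase gene Cdk1 (1.88 ± 0.30), Mcm6 (1.14 ± 0.19) and Mcm2 (1.02 ± 0.21). The list had adjusted p = 1.82e-06, and adjusted p = 0.463 with an estimated correlation. Among 20 fibrosis and stellate cell genes 11 rose, and 15 adjusted over the list alone. Col5a2 stood at 1.41 ± 0.23 and Tgfb1, a cytokine that drives collagen production, at 0.65 ± 0.14 (list adjusted p = 2.03e-05; adjusted p = 0.463 with an estimated correlation). Among 16 lipid droplet and PPARG target genes 8 rose, and 9 adjusted over the list alone, with Fabp4 at 1.66 ± 0.28 and Pparg at 1.12 ± 0.20 (list adjusted p = 2.03e-05; adjusted p = 0.463 with an estimated correlation). Fabp4, Aqp7, at least 3.62-fold higher, and Cidec also made 3 of 5 adipocyte markers that rose, 3 adjusted over the list alone (list adjusted p = 0.0034; adjusted p = 0.463 with an estimated correlation). Among 23 macrophage and Kupffer cell genes 7 rose and 1 fell, and 9 and 1 adjusted over the list alone. Mmp12 stood at 2.77 ± 0.48 and Gpnmb, well above background on 2 of 3 Het low-fat arrays, at 3.23 ± 0.60 (list adjusted p = 0.00181; adjusted p = 0.603 with an estimated correlation). Among 9 cholangiocyte markers Spp1 rose by 2.09 ± 0.46 and Tspan8 by 2.18 ± 0.56, and 5 passed adjusted over the list alone (list adjusted p = 0.00883; adjusted p = 0.603 with an estimated correlation). Without Het high-fat replicate 3 the list had adjusted p = 0.0554.

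Among 18 male-biased genes 7 fell, and 9 adjusted over the list alone, Hsd3b5 and Slco1a1 foremost (list adjusted p = 0.000213; adjusted p = 0.463 with an estimated correlation). Among 15 female-biased genes 8 rose, and 9 adjusted over the list alone, with Cyp2b13 at 2.42 ± 0.53 and Cyp2b9 at 2.05 ± 0.49, again uncertain one by one (list adjusted p = 0.000129; adjusted p = 0.463 with an estimated correlation). Among 18 bile acid genes 3 fell, Slco1a1, Cyp7b1 (-1.40 ± 0.29) and the bile acid enzyme gene Akr1d1 (-0.94 ± 0.20). The phospholipid exporter gene Abcb4 rose by 0.49 ± 0.14, and 3 fell and 1 rose adjusted over the list alone (list adjusted p = 0.021; adjusted p = 0.654 with an estimated correlation). Among 23 acute phase genes 7 rose and 2 fell, and 11 and 3 adjusted over the list alone. Orm3 stood at 1.37 ± 0.26 and the fibrinogen gene Fga at -0.65 ± 0.13 (list adjusted p = 0.0104; adjusted p = 0.386 with an estimated correlation). Among 19 cytokine and NF-kB target genes 4 rose and 2 fell, and 9 and 2 adjusted over the list alone (list adjusted p = 0.04; adjusted p = 0.691 with an estimated correlation). The chemokine gene Ccl4 stood at 1.95 ± 0.36, Il6, well above background on no Het high-fat array, was at least 2.34-fold lower, and Nfkb1 had a log2 fold change of -0.56 ± 0.12 on its brightest probe but 0.77 and 0.34 on others. Of 20 interferon-stimulated genes 3 rose, and 6 rose and 1 fell adjusted over the list alone, with Ifit2 at 0.85 ± 0.17 (list adjusted p = 0.0269; adjusted p = 0.691 with an estimated correlation).

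Among 19 fatty acid synthesis genes 4 rose, and 7 adjusted over the list alone, with the pyruvate kinase gene Pklr at 0.76 ± 0.18 and the citrate lyase gene Acly at 1.05 ± 0.29 (list adjusted p = 0.00883; adjusted p = 0.654 with an estimated correlation). Among 23 cholesterol genes 3 rose, and 1 adjusted over the list alone, with the mevalonate pathway gene Mvd at 1.20 ± 0.34 (list adjusted p = 0.021; adjusted p = 0.691 with an estimated correlation). Pfkl (0.62 ± 0.13) and Pklr rose among 12 glycolysis genes and the glucose transporter gene Slc2a2 fell (-0.85 ± 0.24), and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.0128, and adjusted p = 0.463 with an estimated correlation). Another probe of Slc2a2 stood at -0.08, and its call was lost without any 1 of 5 arrays (limma, adjusted p up to 0.133). Among 17 NRF2 target genes 5 rose and 1 fell, and 6 and 1 adjusted over the list alone. Cbr3 stood at 2.88 ± 0.29 and Srxn1 at 1.23 ± 0.14 (list adjusted p = 0.021; adjusted p = 0.654 with an estimated correlation). Without Het high-fat replicate 3 the call was lost for the cholesterol, fatty acid synthesis, acute phase, cytokine and interferon lists. It was lost without Het low-fat replicate 3 for the cholesterol, fatty acid synthesis, bile acid, glycolysis, NRF2, cytokine and interferon lists, without Het low-fat replicate 1 for the cytokine and interferon lists, and without WT high-fat replicate 3 for the cytokine list (adjusted p up to 0.39). The other 18 lists were not called, with adjusted p between 0.0558 and 0.929, among them T and NK cells at 0.335 and hepatocytes at 0.127. Of 15 hepatocyte genes 4 fell, Cps1 (-0.94 ± 0.16) and the transthyretin gene Ttr (-0.86 ± 0.23) among them.

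In Het livers 2701 genes changed, 1295 higher and 1406 lower, of which 493 and 468 by at least 2-fold. This split also depended on the scaling: 47.9% of the called genes were higher as reported, 53.7% with quantile normalization, 55.5% with scaling to the median and 55.7% with normexp background correction. The count was 1191 without a filter on dim probes, 1560 with only the 2 groups in the fit, 1909 with replicate as a block and 5427 with slide as a random block. It fell to 874 without Het high-fat replicate 1 and to 1097, 1635 and 1519 without Het low-fat replicates 1, 2 and 3. The 5427 with slide as a random block carry the same limit as the count with that block in WT. In all 37 of the 61 called genes named in the text passed whichever array was left out. The call of Abcb4 was lost without any 1 of 7 arrays (limma, adjusted p up to 0.142). Those of Mvd and Tspan8 were each lost without any 1 of 5, and that of Acly without any 1 of 4. The log2 fold changes correlated with the GC content of the probes at r = 0.22 across genes, which are not independent replicates, against 0.06 in WT.

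Probes with runs of alternating G and T bases were lower on the high-fat arrays of both genotypes. The 35 tested probes with a run of 9 or more had a median log2 fold change of -2.10 in WT and -2.33 in Het, 18 and 26 of them called lower and 0 called higher. The 16328 probes with runs of 0 to 5 had medians of -0.05 and 0.00. In WT the change was -3.50 ± 0.52 for Stag2, a cohesin gene, -3.31 ± 0.49 for Dennd3, -3.25 ± 0.65 for the gastrin gene Gast, well above background on 2 of 3 high-fat arrays, and -3.18 ± 0.47 for the olfactory receptor gene Olfr1410. In Het it was -3.92 ± 0.47 for Olfr1410, -3.92 ± 0.87 for the integrin gene Itgb3, -3.45 ± 0.64 for Bcorl1 and -3.43 ± 0.49 for Dennd3. Other probes of the same genes gave 0.39 for Dennd3 in WT and, in Het, 0.42 for Dennd3, 0.14 for Itgb3 and 0.04 for Bcorl1. Over the 14 genes with both kinds of probe the mean change of the 2 genotypes had a median of -1.91 on the probes with the run and of -0.02 (95% bootstrap interval -0.14 to 0.17) on the others. Junb, an immediate early gene with a run of 13 bases, was lower on both kinds, at -2.32 and -1.15. Without the probes that hold a run of 8 or more, an alternative added after the data were seen, 957 genes were called in WT and 2673 in Het.

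**Figure D3:**
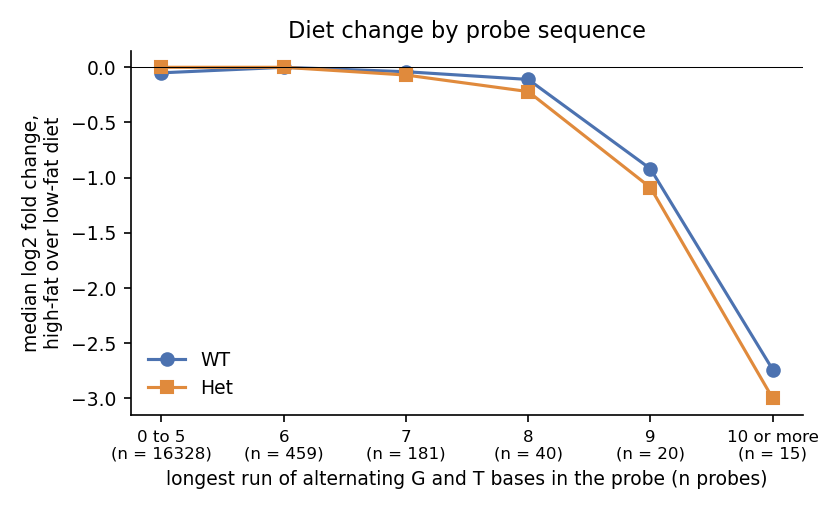
Median log2 fold change, high-fat over low-fat diet, of the tested probes by the length of their longest run of alternating G and T bases, in WT and Het livers, with the number of probes under each length. The medians lay near 0 up to a run of 7 and reached -2.74 and -3.00 in the 15 probes with a run of 10 or more.

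The diet effects of the 2 genotypes were then set side by side. Tinag, Ly6d, Gipc2, Gprc5b, Gpnmb and Mmp12 were called higher in both, and Moxd1, Hsd3b4 and Cyp7b1 lower in both. In all, 365 genes were higher in both genotypes and 353 lower in both, where independent lists of those sizes would share 35 and 45, and 1 gene was called in opposite directions. Across the 17043 genes the log2 fold changes correlated at r = 0.74 (Spearman rho 0.71). The comparisons share no array, but they share the scan days and the probe sequences. Genes are not independent replicates. Another 290 genes were called in WT alone and 1982 in Het alone, and 1900 of the latter had the same sign in WT. A call in 1 genotype alone is not a difference between genotypes; of those 1982 genes, 323 had an unadjusted interaction p below 0.05, and none passed adjustment.

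**Figure D4:**
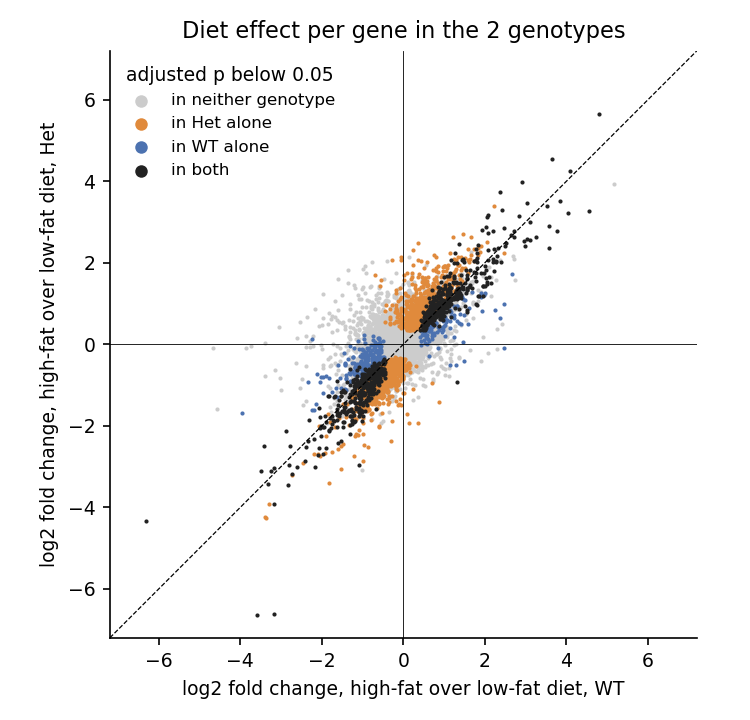
Log2 fold change of each of the 17043 genes, high-fat over low-fat diet, in WT (horizontal) against Het livers (vertical), coloured by where the gene had an adjusted p below 0.05, with the diagonal of equal change dashed. Of the 2991 genes called in either genotype, 96.5% had the same sign in both.

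The next comparison asks how Het differed from WT livers on the high-fat diet. Genes of cholesterol synthesis and male-biased liver genes were lower in Het as lists, though neither list passed with an estimated correlation. No single gene passed adjustment. Among the 5 lowest p values upwards were 1700072F12Rik and the microtubule gene Tekt1, each well above background on the 3 Het high-fat arrays and on no WT high-fat array, and at least 1.42-fold and 1.26-fold higher. Cxcr2, a chemokine receptor gene of neutrophils, differed by 1.75 ± 0.31, the anchoring protein gene Akap6 by 0.75 ± 0.14 and the secreted factor gene C1qtnf1 by 0.66 ± 0.11. Of the 3 WT high-fat arrays, Cxcr2 was well above background on 1 and Akap6 on 2. In the other direction stood Hsd3b4 at -3.45 ± 0.66 and the transcript AK138477 at -1.47 ± 0.26. They were followed by Cish, a feedback inhibitor that STAT5 induces, at -1.28 ± 0.24, the transcript AK082839 at -0.73 ± 0.11 and the semaphorin receptor gene Plxna2 at -0.62 ± 0.12 (adjusted p = 0.345 for each of the 10). Of the gene lists, the 23 genes of cholesterol synthesis and uptake were lower, with a median of -0.21 and Cyp51 at -0.67 ± 0.23 (list adjusted p = 0.00994; adjusted p = 0.878 with an estimated correlation). The 18 male-biased genes were lower with a median of -0.10, Hsd3b5 standing at -3.91 ± 0.82 and Slco1a1 at -1.77 ± 0.55 (list adjusted p = 0.0442; adjusted p = 0.878 with an estimated correlation). None of their members passed over all genes, and adjusted over the list alone 0 and 1 did. On the slide that held both genotypes, which gives the value with slide as a block, the medians were -0.27 and -0.24, from 1 WT array against 3 Het arrays. The other 32 lists were not called, with adjusted p between 0.0748 and 0.899.

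With limma 0 genes passed, while 1475 had an unadjusted p below 0.05, 927 higher and 548 lower, and the trend and robust form of the test gave 0 and 1470. Quantile normalization called AK082839 (-0.78, adjusted p = 0.0495) and Olfr167 (lower, adjusted p = 0.0279), the latter named after its value was seen and well above background on no Het high-fat array. Without WT high-fat replicate 3 the count was 48, without Het high-fat replicate 2 it was 2 (Cd163 and Fabp3, also named afterwards) and without Het low-fat replicate 2 it was 1 (1700072F12Rik). The cholesterol call was lost without WT high-fat replicate 1 or 3 or Het high-fat replicate 1 or 2 (adjusted p up to 0.171). The male-biased call was lost without any 1 of 7 arrays (WT high-fat replicates 1 and 3, Het high-fat replicate 1, WT low-fat replicates 1 and 3, and Het low-fat replicates 1 and 3; adjusted p up to 0.261). With slide as a block the 13 genes named here kept their direction (lowest adjusted p = 0.599). The differences correlated with the GC content of the probes at r = 0.30 across genes.

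On the low-fat diet, markers of lymphocytes were lower in Het than in WT livers, and acute phase genes slightly higher. Of the lists called here only the acute phase list passed with an estimated correlation. Of 15 T and NK cell genes the median difference was -0.55, with the T cell surface gene Cd2 at -0.73 ± 0.26 and the kinase gene Lck at -0.69 ± 0.28 (list adjusted p = 1.75e-06; adjusted p = 0.474 with an estimated correlation). Of 9 B cell and plasma cell genes it was -0.68, with Mzb1 at -1.47 ± 0.53 and the immunoglobulin joining chain gene Jchain at -1.71 ± 0.63 (list adjusted p = 5.07e-07; adjusted p = 0.474 with an estimated correlation). The acute phase list had a median of 0.13 (list adjusted p = 0.000187; adjusted p = 0.0486 with an estimated correlation), with Socs3 standing at 0.63 ± 0.24 and Saa2 at 0.80 ± 0.35. Immediate early genes were higher with a median of 0.26, the growth gene Myc at 0.87 ± 0.38 and Egr2 at 0.74 ± 0.40 (list adjusted p = 0.000403; adjusted p = 0.474 with an estimated correlation). Fibrosis and stellate cell genes had a median of 0.17, with Des at 0.24 ± 0.16 (list adjusted p = 0.000403; adjusted p = 0.668 with an estimated correlation), and ER stress genes 0.18, with Chac1 at 0.66 ± 0.27 (list adjusted p = 0.00106; adjusted p = 0.474 with an estimated correlation). The clock genes stood at a median of 0.18, with Bhlhe40 at 0.28 ± 0.21 (list adjusted p = 0.0455; adjusted p = 0.668 with an estimated correlation), and the male-biased genes at -0.14, with Moxd1 at -2.04 ± 0.81 (list adjusted p = 0.0322; adjusted p = 0.818 with an estimated correlation). Cd2 and Moxd1 were each well above background on 2 of 3 Het low-fat arrays. No member of these 8 lists passed, over all genes or adjusted over the list alone.

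The medians of the T and NK cell list lay at 0.67, 0.28 and 0.05 on the 3 WT low-fat arrays, as log2 deviations from the mean of the 12 arrays, and at -0.79, 0.06 and 0.01 on the 3 Het arrays. Those of the B cell list lay at 1.24, -0.26 and 0.07 in WT and at -0.50, 0.00 and -0.52 in Het. The SD of the negative control spots was 3.15, 2.77 and 6.35 intensity units on the WT low-fat arrays and 6.19, 6.23 and 3.48 on the Het low-fat arrays. Leaving out any 1 array kept both calls, with list medians from -0.63 to -0.31 for T and NK cells and from -1.03 to -0.18 for B cells. On the slide with both genotypes, from 3 WT arrays against 1 Het array, the medians were -0.98 for T and NK cells, -0.82 for B cells, 0.74 for immediate early genes, 0.39 for fibrosis genes and 0.11 for acute phase genes. For the ER stress, clock and male-biased lists they were 0.11, 0.10 and -0.20 (adjusted p = 0.187, 0.199 and 0.16). As these values rest on 1 Het array, the lowest one for T and NK cells, they do not strengthen the calls. The calls of immediate early and fibrosis genes were lost without Het low-fat replicate 1 (adjusted p = 0.128 and 0.2) and that of ER stress without WT low-fat replicate 1 or Het low-fat replicate 2 (adjusted p up to 0.251). The male-biased call was lost without WT low-fat replicate 2 or Het low-fat replicate 1 or 2, and the clock call without Het high-fat replicates 1 or 3, WT low-fat replicate 2 or Het low-fat replicates 1 or 3 (adjusted p up to 0.924 and 0.908). The other 26 lists were not called, with adjusted p between 0.0562 and 0.858.

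**Figure D5:**
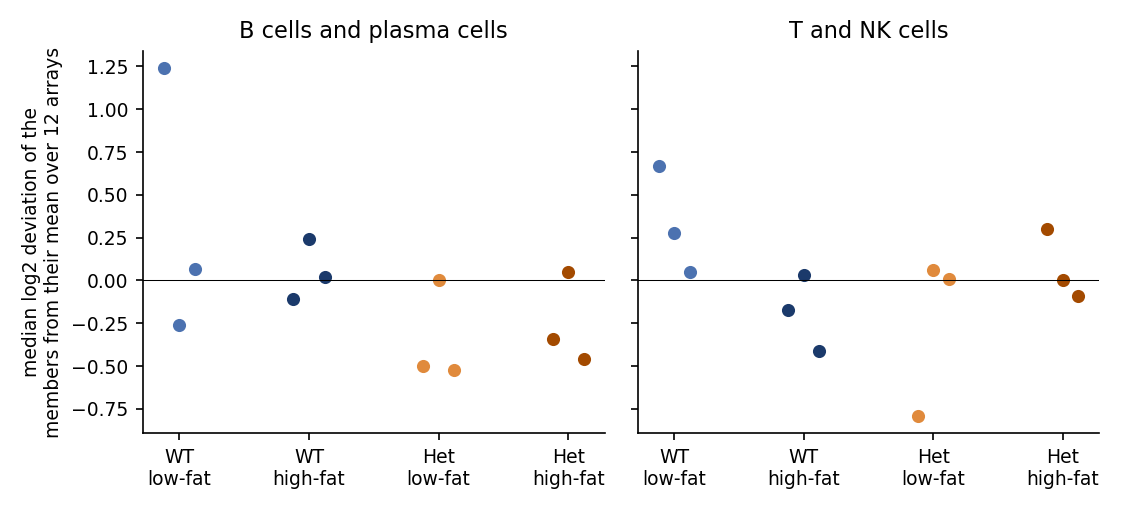
Median log2 deviation of the B cell and plasma cell genes and of the T and NK cell genes from their mean over the 12 arrays, with 1 point per mouse in each of the 4 groups. WT low-fat replicate 1 was the highest array for both lists, at 1.24 and 0.67, and Het low-fat replicate 1 the lowest for T and NK cells, at -0.79.

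Among single genes on the low-fat diet, the lowest p values upwards belonged to Lix1 (0.82 ± 0.17), the neuronal filament gene Prph (1.17 ± 0.24), the transcript NAP100574-001 (1.64 ± 0.36), the p53 target gene Phlda3 (0.81 ± 0.18) and the myosin light chain gene Myl7 (1.24 ± 0.28). Of the 3 WT low-fat arrays, Prph was well above background on 2 and NAP100574-001 on 1. Downwards they were the transcripts TC1473353 (at least 1.41-fold), ENSMUST00000085415 (-0.71 ± 0.15), AK162987 (-0.53 ± 0.12), LOC673099 (-1.94 ± 0.45) and AK036268 (at least 1.46-fold), the last on a probe with a run of 9 alternating G and T bases. TC1473353 and AK036268 were well above background on no Het low-fat array, and ENSMUST00000085415 on 1 of 3. With limma 0 genes passed (adjusted p = 1 for each of the 10), 341 had an unadjusted p below 0.05, 141 higher and 200 lower, and the trend and robust form gave 0 and 290. With slide as a block 1 gene was called, Clca4b at 2.32 (adjusted p = 0.026), named after its value was seen. Of the Het low-fat arrays it was well above background on replicate 1 alone, the only Het array of the shared slide. Without that array the same gene was called lower in Het, and as it was not well above background on the other 2, no exact fold is given.

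Over both diets, genes of B cells and male-biased genes were lower in Het and genes of fibrosis and stellate cells higher as lists, though none passed with an estimated correlation. Again no single gene passed adjustment. The 9 B cell genes had a median of -0.50, with Jchain at -1.54 ± 0.44 (list adjusted p = 7.81e-05; adjusted p = 0.829 with an estimated correlation). The 20 fibrosis genes had 0.20, with Tgfb1 at 0.26 ± 0.10 (list adjusted p = 0.000235; adjusted p = 0.829 with an estimated correlation), and the 18 male-biased genes had -0.13, with Hsd3b5 at -2.18 ± 0.58 (list adjusted p = 0.000554; adjusted p = 0.829 with an estimated correlation). The clock genes stood at 0.33, with Per3 at 0.60 ± 0.27 (list adjusted p = 0.0158; adjusted p = 0.829 with an estimated correlation), and the acute phase genes at 0.13, with Orm2 at 0.30 ± 0.09 (list adjusted p = 0.0158; adjusted p = 0.336 with an estimated correlation). Bile acid genes had a median of -0.12, with Slco1a1 at -0.99 ± 0.39 (list adjusted p = 0.0162; adjusted p = 0.829 with an estimated correlation). Cholesterol genes had -0.11, with Pmvk at -0.28 ± 0.13 (list adjusted p = 0.0391; adjusted p = 0.829 with an estimated correlation), and lipid droplet genes 0.16, with Apoa4 at 0.74 ± 0.29 (list adjusted p = 0.0466; adjusted p = 0.829 with an estimated correlation). Adjusted over the list alone 1 B cell gene was lower and no member of the other 7 lists passed. With slide as a block the medians were -0.58, 0.34, -0.29, 0.54, 0.21, -0.20, -0.02 and 0.17 in this order, the cholesterol and lipid droplet calls being lost (adjusted p = 0.43 and 0.404). The other 26 lists were not called, with adjusted p between 0.107 and 0.702.

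The single genes of lowest p over both diets were NAP100574-001 (1.61 ± 0.26), C1qtnf1 (0.48 ± 0.08), DXBay18 (1.05 ± 0.20), the Polycomb gene Pcgf2 and the G protein gene Gnal upwards, and AK082839 (-0.46 ± 0.08), Sirt1, Tspan1 (-0.73 ± 0.16), Trim67 and Hsd3b4 (-1.92 ± 0.47) downwards. Several of these were not well above background throughout, in the order WT low-fat, WT high-fat, Het low-fat and Het high-fat. Gnal was so on 1, 0, 0 and 3 arrays, Pcgf2 on 1, 0, 1 and 3, Trim67 on 3, 1, 1 and 0, NAP100574-001 on 1, 1, 3 and 3, and DXBay18 on 2, 3, 3 and 3. No differences are given for the first 3, which in at least 1 group were so on no array. With limma 0 genes passed (lowest adjusted p = 0.695), 824 had an unadjusted p below 0.05, 509 higher and 315 lower, and the trend and robust form gave 0 and 778. With slide as a block Clca4b alone was called (adjusted p = 0.0295), which was well above background on no high-fat array, and without WT high-fat replicate 3 the count was 7. Leaving out 1 array kept the B cell and fibrosis calls, while the male-biased call was lost without WT low-fat replicate 2 (adjusted p = 0.132). Lost too were the acute phase call without WT or Het high-fat replicate 3 (up to 0.138) and the clock call without those or WT low-fat replicate 2 or Het low-fat replicate 3 (up to 0.258). The bile acid call was lost without any of 5 arrays (WT high-fat replicates 1 and 3, Het high-fat replicate 1, WT low-fat replicate 2 and Het low-fat replicate 2; up to 0.153), and the cholesterol call without any of 7 (WT high-fat replicates 1 and 3, Het high-fat replicates 1 and 2, WT low-fat replicates 1 and 2 and Het low-fat replicate 3; up to 0.375). The lipid droplet call was lost without any high-fat array but Het replicate 2, and without WT or Het low-fat replicate 2 (up to 0.705).

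The last comparison asks whether the genotype difference itself depended on diet. T and NK cell genes had a genotype difference higher by a median of 0.72 on the high-fat than on the low-fat diet (list adjusted p = 0.000419; adjusted p = 0.978 with an estimated correlation). That of ER stress genes was lower by a median of -0.28 (list adjusted p = 0.00368; adjusted p = 0.978 with an estimated correlation) and that of cholesterol genes by -0.22 (list adjusted p = 0.00638; adjusted p = 0.978 with an estimated correlation). No member of the 3 lists passed, over all genes or adjusted over the list alone, and the other 31 lists had adjusted p between 0.0545 and 0.942. With slide as a block, added after the data were seen, the medians were 1.56 for T and NK cells, -0.39 for cholesterol genes and -0.11 for ER stress genes, the last no longer called (adjusted p = 0.19). Among single genes the mean log2 signals, in the order WT low-fat, WT high-fat, Het low-fat and Het high-fat, were 2.28, 1.21, 2.87 and -0.08 for Cish, and -2.67, -1.36, -1.43 and -2.35 for Myl7. They were -3.56, -2.26, -2.62 and -3.14 for the glypican gene Gpc3, -1.72, -1.08, -1.27 and -1.56 for the Notch target gene Heyl, and 1.38, 1.69, 1.60 and 1.06 for Plxna2, all with a lower genotype difference on the high-fat diet. With a higher one they were -3.15, -3.59, -3.68 and -3.14 for AK162987. The other 4 with a higher one, Akap6, the amine oxidase gene Aoc2, the lymphocyte receptor gene Slamf7 and Ccdc96, were well above background on every Het high-fat and no Het low-fat array. Aoc2 was so on no WT high-fat array either, and no means are given for these 4. The lowest signal well above background was 18.71, 17.26 and 29.03 intensity units on Het high-fat and 56.25, 55.61 and 30.57 on Het low-fat arrays. Detection on 1 diet alone is therefore no measure of a difference in expression here. The interaction was -1.87 ± 0.34 for Cish and 0.98 ± 0.17 for AK162987 (adjusted p = 0.944 for each of the 10). With limma 0 genes passed, 828 had an unadjusted p below 0.05, 541 higher and 287 lower, and the trend and robust form gave 0 and 764. Without WT high-fat replicate 3 there were 3 calls (H1f1, LOC545547 and Lrrc66) and without Het low-fat replicate 1 there was 1 (Clca4b), named after their values were seen. The cholesterol call was lost without Het high-fat replicate 2, WT low-fat replicate 3 or Het low-fat replicate 1 (adjusted p up to 0.197) and the ER stress call without WT low-fat replicate 1 or Het low-fat replicate 2 (up to 0.0866).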

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

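The results in this part came from planned tests, except those with slide as a block for the interaction and with array trends removed, which were chosen after the results were seen.

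The genotype difference of 3 gene lists differed between the diets in the interaction test. For T and NK cell genes it was higher on the high-fat than on the low-fat diet by a median of 0.72 (limma and camera, list adjusted p = 0.000419; adjusted p = 0.978 with an estimated correlation), from 0.45 to 0.88 when each array was left out in turn, all still called. For ER stress genes the median was -0.28 (list adjusted p = 0.00368; adjusted p = 0.978 with an estimated correlation), and the call was lost without WT low-fat replicate 1 or Het low-fat replicate 2 (adjusted p up to 0.0866) and with slide as a block (-0.11, adjusted p = 0.19). For cholesterol genes it was -0.22 (list adjusted p = 0.00638; adjusted p = 0.978 with an estimated correlation), lost without Het high-fat replicate 2, WT low-fat replicate 3 or Het low-fat replicate 1 (adjusted p up to 0.197).

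The T and NK cell result goes with lower lymphocyte genes in Het livers on the low-fat diet, where 20 of the 24 measured T, NK and B cell genes were lower. Signals not above background are argued against as the whole cause, since 21 of the 24 members were well above background on all 12 arrays. Those 21 had a median of -0.55, with a 95% bootstrap interval, drawn over genes and not over mice, of -0.68 to -0.38. They are most of the 24, which also had a median of -0.55, so this value is no separate support. Noise that differed between the arrays was not tested for these genes. A difference between slides stays open: with slide as a block the median was -0.91, but the shared slide held only 1 Het array, Het low-fat replicate 1. A smaller share of lymphocytes in these livers may also account for the pattern and stays open. The 28 lymphocyte genes measured outside the fixed lists had a median of -0.27, 25 of them lower (camera p = 3.62e-10, and p = 0.0452 with an estimated correlation). Genes are not independent replicates. As log2 deviations, the medians of these genes lay at 0.37, -0.07 and -0.13 on the WT and at -0.42, 0.06 and -0.23 on the Het low-fat arrays. Apart from replicate 1 of each genotype these values overlapped. With array trends removed the low-fat medians were -0.52 for T and NK cells and -0.68 for B cells. The 5 measured red blood cell genes had a low-fat median of -0.08 with the trends left in (list adjusted p = 0.67; adjusted p = 0.953 with an estimated correlation).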

How the results depend on the processing

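The settings with array trends removed, array brightness or background noise as a covariate, and probes with G and T runs left out were chosen after the data were seen. For diet in WT the count of 1009 genes was 156 without a filter on dim probes, where more genes were tested, 598 with only the compared groups in the fit, 3595 with slide as a random block (estimated correlation -0.18), 1773 with array brightness and 2029 with background noise as a covariate. For diet in Het the count of 2701 was 1191, 1560 and 5427 under the first 3 of these. Diet differed only between slides, and a negative correlation within slides makes such differences look more precise. The larger counts with slide as a random block are therefore no stronger evidence of diet effects. The causes of the other differences, the lower counts without a filter included, were not tested. Quantile normalization called 2 genes by genotype on the high-fat diet, and slide as a fixed block called 1 on the low-fat diet and 1 over both. When each array was left out in turn the counts ranged from 186 to 1127 for diet in WT, from 874 to 2881 for diet in Het, from 0 to 48 for genotype on the high-fat diet, from 0 to 1 on the low-fat diet, from 0 to 7 over both diets and from 0 to 3 for the interaction. The lowest diet counts came without WT high-fat replicate 3 and Het high-fat replicate 1, the 48 and 7 without WT high-fat replicate 3. Median scaling moved the median log2 change of all genes from -0.05 to 0.07 for diet in WT, from 0.03 to -0.08 for genotype on the high-fat diet and from 0.03 to -0.09 for the interaction.

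Same-numbered arrays were no more alike than others: over 18 same-numbered pairs the deviations from the group means correlated between -0.47 and 0.46 across genes, with a median of -0.03 against 0.04 for other pairs, and the own number correlated best in 8 of 36 cases. These values cannot tell whether the numbers pair the mice by design. With the replicate block 549 genes were called for diet in WT, 498 of them among the 1009, and 1909 for diet in Het, 1825 of them among the 2701. Scan date as a batch was not run, since all arrays of a diet share 1 scan day. The series table holds the scanner values, so its counts, identical to those given, test nothing.

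Of 53 list calls 2 held with an estimated correlation, 47 with quantile normalization, 51 with the replicate block and 50 with array trends removed, and none turned direction. Over the genotype comparisons and the interaction 21 lists were called, 1 with an estimated correlation and 39 with slide as a fixed block, which kept 15 of the 21, though each shared slide holds 1 array of 1 genotype against 3. Leaving out 1 array gave from 48 to 70 list calls in all and from 16 to 34 for genotype and interaction. The Sirt1 difference over both diets stayed between -0.48 and -0.39 on the brighter probe (highest exact permutation p = 0.01) and between -0.69 and -0.58 on the other. The correlation of the diet effects across genes lay between 0.67 and 0.77 with 1 array left out, and was 0.75 with quantile normalization.

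Of 113 named values past the threshold, 45 were past it in every alternative, arrays left out included. Over all 179 named values and their alternatives 4644 kept direction and side of the threshold, 444 kept direction and were no longer past it, 19 came past it and 12 turned direction. With slide as a block the 13, 22, 18 and 10 named genes of the genotype comparisons and the interaction kept their direction (lowest adjusted p = 0.599, 1, 0.959 and 0.768). Values that turned direction were those of Dennd3 in WT (0.39) and Het (0.42), Itgb3 (0.14) and Bcorl1 (0.04) in Het, on another probe and with G and T runs left out, and of Nfkb1 in Het, 0.77 and 0.34 on other probes, 0.08 as the mean of probes and 0.06 with array trends removed. For the first 3 genes the run in the probe separates the values; for Nfkb1 the cause was not tested. Signal over background limits dim genes: 58.0% to 71.6% of spots were well above background, and for genes below it on every array of 1 of 2 compared groups the fold is a bound.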

Other observations

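In this part the tests on probe sequence, on the other probes of the same genes and on the share of hepatocyte RNA were chosen only after the results were seen. The same holds for the settings with array trends removed and with background noise as a covariate.

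Several groups whose lists were not called held single genes that passed for diet (limma, adjusted over all genes). Among steroid enzymes Ugt2b1 fell in both genotypes (-1.09 ± 0.18 in WT and -1.03 ± 0.18 in Het), as did the steroid reductase gene Srd5a1 (-0.74 ± 0.15 and -0.93 ± 0.15), while the oestrogen sulfotransferase gene Sult1e1 rose (1.57 ± 0.40 and 1.59 ± 0.40). The xenobiotic enzyme gene Cyp3a11 rose in both (1.29 ± 0.24 and 1.18 ± 0.24) and Cyp2b10 in Het (2.10 ± 0.58), both uncertain as single genes among close relatives. The apolipoprotein gene Apom was lower in both (-0.50 ± 0.13 and -0.67 ± 0.13). Among endothelial genes the VEGF receptor gene Kdr fell in both (-0.60 ± 0.15 and -0.49 ± 0.15), and the lymphatic and sinusoidal gene Lyve1 rose in WT (1.24 ± 0.32). In Het Vwf rose (0.81 ± 0.25), and the cadherin gene Cdh5 fell on its brightest probe (-0.72 ± 0.17) but stood at -0.01 on another. In Het the peroxisome gene Pex11a rose by 1.12 ± 0.16 and Sirt7, a relative of Sirt1, fell by 0.55 on the log2 scale. Many of these calls were fragile. Without any 1 of 12 arrays the call of Apom in WT was lost, without any 1 of 11 that of Sult1e1 in WT, and without any 1 of 10 those of Lyve1, Vwf and, in Het, Kdr (adjusted p up to 0.154). Kdr in WT was lost in 8 cases, Srd5a1 and Cyp3a11 in WT and Sult1e1, Cyp2b10 and Sirt7 in Het in 4 each, and Cdh5 in 2.

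Male-biased genes were lower and female-biased genes higher on the high-fat diet, with a gap between the list medians of 1.52 averaged over the genotypes. The female-biased genes Cyp3a44, Cyp3a16, Cyp2b9 and Cyp2b13 are close relatives of Cyp3a11, which rose in both genotypes, or of Cyp2b10, which rose in Het. Whether signal shared within these families makes part of the female-biased rise was not tested. A trend of the arrays on probe GC content or brightness is argued against as the whole cause, since the gap was 1.56 with those trends removed. A smaller share of hepatocyte RNA that raised the markers of all other cell types alike is argued against as the whole cause. Fibrosis and stellate cell genes stood 0.79 above endothelial genes, with medians of 0.66 and -0.18 in WT and 0.71 and -0.04 in Het. The 95% bootstrap intervals, drawn over genes, were 0.45 to 0.92 against -0.31 to 0.11, and 0.46 to 0.98 against -0.33 to 0.28. A smaller share through gains of only some other cell types was not tested directly. It would lower hepatocyte genes and not raise them, while the female-biased genes had a median of 0.9 in each genotype. Their 95% bootstrap intervals, drawn over genes, were 0.09 to 1.26 in WT and 0.72 to 1.59 in Het. So far as hepatocytes express these genes, this argues against such a share as the whole cause. A part in the fall of the male-biased genes stays open. Weaker growth hormone signalling through STAT5 may be a cause: 6 target genes outside the male-biased list, Igf1, Igfals, Socs2, Onecut1, Ghr and Prlr, had a median of -0.59 in WT and -0.48 in Het (camera p = 0.0145 and 0.0286, and p = 0.154 and 0.196 with an estimated correlation). None of the 6 passed alone over all genes in the limma fit (lowest adjusted p = 0.0531 in WT and 0.0944 in Het). Cish, named after its values were seen, had -1.08 ± 0.24 and -2.95 ± 0.24. Between the genotypes on the high-fat diet Cish stood at -1.28 ± 0.24 and did not pass (limma, adjusted p = 0.345). The 6 targets had a median of 0 in that comparison, so there Cish did not move with them. Scan day stays open for this pattern, as for every diet effect here.

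Probes with long runs of alternating G and T bases were lower on the high-fat arrays. That the transcripts fell is argued against for the set, since other probes of the same 14 genes had a median of -0.02, although Junb (-1.15) and Stag2 (-0.58) were lower there too. An effect of the probe sequence that differed between the arrays of the 2 scan days may be the cause: the 35 probes had a median of -2.26 over both genotypes, and 15 probes with runs of alternating C and A bases one of 0.18. Per array the median deviation of the 35 probes lay between -1.26 and -0.71 on the high-fat and between 0.05 and 1.61 on the low-fat arrays. It also varied within each scan day. The 2 dimmest low-fat arrays, WT replicate 2 and Het replicate 3, had 0.05 and 0.34, the others 1.12 to 1.61. The 2 brightest high-fat arrays, WT replicate 2 and Het replicate 3, had -0.71 and -0.88, the others -1.26 to -1.07. Those high-fat arrays were brighter than those low-fat arrays yet lay lower, so brightness alone does not order the 2 days. An effect of the single array was not tested. Diet and scan day cannot be told apart for this set.

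Other splits of the arrays were counted beside each comparison. For diet, 1 of the 10 splits of the 6 arrays reached the real count in each genotype, the real one itself, with 1009 genes in WT against at most 12 and 2701 in Het against at most 2, and 10 splits are too few for a share under 0.05. For genotype, genes at an unadjusted p below 0.05 were counted. On the high-fat diet 2 of 10 splits reached the real 1475, the highest other giving 1749, and on the low-fat diet 7 of 10 reached the real 341, the highest other giving 3684, again too few splits for a share under 0.05. The low-fat split of 3684 genes set WT low-fat replicates 1 and 2 and Het low-fat replicate 3 against the rest. These are the low-fat arrays with the lowest SD of negative control spots, so this split ran along the noise of the arrays. With that noise as a covariate, an alternative added after the data were seen, 0 genes were called by genotype on the low-fat diet and 835 had an unadjusted p below 0.05. The high-fat split of 1749 set WT high-fat replicate 1 and Het high-fat replicates 1 and 2 against the rest, the high-fat arrays whose signals correlated most with probe GC content across genes (0.19, 0.26 and 0.37). For the real genotype groups on the high-fat diet, 1143 genes in place of 1475 had an unadjusted p below 0.05 with array trends removed. Over both diets 32 of 100 splits reached the real 824 (highest other 4894), and for the interaction 31 of 100 reached the real 828 (highest other 3172), so chance cannot be excluded for these counts.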
